A study of Homo sapiens with 6 samples.

How the data were processed

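Poly(A) RNA sequencing libraries were made from total RNA with a stranded mRNA kit, per the labels' protocols, from THP-1-derived macrophages 24 h after siRNA transfection. The authors deposited 1 table of TPM per gene with a column for each of the 6 libraries, to 2 decimals. The submitters' processing notes name fastp, HISAT2, StringTie and the GRCh38 build with no versions; the annotation release and the program that gave the TPM are not given in the sources used here. Each column summed to 1000000 within rounding. TPM divide by transcript length and library total, so they show shares of the transcript pool, keep no depth, and let a change in abundant transcripts shift the others. Because depth is unknown, no interval or detection limit from counts is given, and the precision of low genes could not be set.

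The table held 63241 gene rows, after 21 rows with no gene ID (19 blank and 2 text fragments) were left out. A symbol was given for 42640 genes, and 58228 IDs were found in GENCODE release 29, from which coordinates, biotypes and 3' UTRs were taken. Groups came from the sample titles. The title, library name and genotype agree for every sample, and the treatment field of siDUSP6 replicates 2 and 3 names other DUSP genes; no sample was moved or left out for that.

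Values were analysed as log2(TPM + 1) in limma 3.58.1 (R 4.3.3), with group as the only term, empirical Bayes moderation with a variance trend, genes with a mean of at least 1 TPM over the 6 libraries, and Benjamini-Hochberg adjustment, with calls at an adjusted p of 0.05. Tests were two-sided. Fold changes are on the log2(TPM + 1) scale and understate the change of low genes. With 3 against 3 libraries an exact two-sided permutation test of 1 gene cannot give a p under 0.1, so p-values rest on limma's model. The 36 gene lists, which name 750 members with repeats, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Of the 8 lists that lost their call with it, the estimated correlation lay below 0.01 for inflammasome (-0.0853), autophagy (-0.001) and ribosomal genes (-0.0037). It lay above 0.01 for NRF2 and metal response (0.1481), MHC class I (0.0818), chemokine (0.0702), heat shock (0.0632) and oxidative phosphorylation genes (0.0228). For the lists below 0.01 a lost call therefore need not come from correlated members. For the others correlated members are not excluded. Lists are summarised by the median log2 fold change of their measured members, those with a mean of at least 1 TPM. A summary of the lists short of the threshold by their camera p instead was tried after their medians were seen to change sign between settings, and was not used.

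Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named were DUSP6, DUSP7 and DUSP8; the 12 largest rises and 12 largest falls among called genes with a symbol, a mean of at least 5 TPM and non-overlapping groups; in each list up to 4 called members with the largest change, or the 2 with the smallest p where none was called; and MRC1, CD163, CD80, CD86, TNF, IL1B, IL10 and ARG1. The file gives no biotype, so U2 and NCF1C qualified.

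Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, TPM recomputed without mitochondrially encoded and the 50 most abundant genes, no variance trend, a robust trend, the replicate number as a block, protein-coding genes only, each library left out in turn, and the other list tests. A range over all alternatives covers those that keep the gene or list. The fit was tested on simulated data for siDUSP6 against siNC over 14602 genes. These had the real genes' means and the spreads given by the empirical Bayes moderation. The fit recovered 6%, 32%, 68% and 92% of 50 genes each changed 1.1-fold, 1.25-fold, 1.5-fold and 2-fold. Moderated spreads differ less between genes than unmoderated ones, so the rates of this test may be too favourable. In that test 6 of 105 calls (5.71%) were false, and 0 genes and 0 lists were called with no change planted. The simulated genes varied independently of each other, so this does not show how often camera calls lists whose genes vary together.

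Seed matches were sought with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, by comparing fold changes, corrected for 3' UTR length and GC content, between genes with and without each 7-mer in the annotated 3' UTR, and ranking 7-mers by the z of that comparison. This covered 9254 genes with a mean of at least 5 TPM and a 3' UTR of at least 50 bases, and 16096 7-mers found in at least 50 genes. For every seed, carriers of its 7-mer sites among called genes were also set against the share expected from 3' UTR length and GC content. On simulated data all 18 planted 7-mers, each with a fall of 0.1 on the log2 scale, ranked first. The highest absolute z over shuffled genes was 5.144. The shifts of the leading 7-mers reported below were smaller (-0.0225 and -0.0231), and recovery of shifts of that size is not shown. Figures were drawn with matplotlib 3.10.9.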

Results

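RNA sequencing compared THP-1-derived macrophages 24 h after transfection with a negative control siRNA (siNC) or an siRNA against DUSP6 (siDUSP6), with 3 libraries in each group. THP-1 is an established human monocytic leukaemia cell line whose cells can be differentiated into macrophage-like cells. DUSP6 encodes a cytoplasmic phosphatase that removes phosphate from ERK1 and ERK2. The series title places the comparison in a study of macrophage polarization, ERK and epithelial-mesenchymal transition (EMT) in adenomyosis. Values were TPM, a length-scaled share of each library's transcripts, which keep no sequencing depth, so the depth of each library is unknown. Between 14487 and 14680 genes per library reached 1 TPM, and log2(TPM + 1) values correlated across genes at 0.984 to 0.985 within siNC, 0.982 to 0.983 within siDUSP6 and 0.981 to 0.983 between the groups. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

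DUSP6 mRNA fell in the siDUSP6 libraries, from 368 ± 9.22 TPM in siNC to 222 ± 4.65 TPM (SD, n = 3 each). This is a log2 fold change of -0.73 (SE 0.0267, limma adjusted p = 8.667e-05), or a change of -39.7% in mean TPM, so most of the transcript remained. DUSP6 (ENSG00000139318) lies on the minus strand of chromosome 12 from 89347232 to 89353271 in GRCh38. The title, library name and genotype of all 3 siDUSP6 libraries name DUSP6, whereas the treatment field of replicates 2 and 3 names DUSP7 and DUSP8. DUSP6 stood at 227, 218 and 222 TPM in siDUSP6 replicates 1, 2 and 3, against 359 to 378 TPM in the siNC libraries. DUSP7, a phosphatase of the same ERK-directed family, also fell, from 48.9 ± 1.57 to 38.8 ± 1.35 TPM (log2 fold change -0.33, SE 0.0423, limma adjusted p = 0.0111), with 39.6, 39.5 and 37.2 TPM in replicates 1, 2 and 3. The DUSP7 call was lost without siNC replicate 1 (adjusted p = 0.05353) or siNC replicate 2 (adjusted p = 0.05183), and over all alternatives its adjusted p ranged from 0.005523 to 0.05978. DUSP8 was low in both groups, at 1.78 ± 0.358 and 1.56 ± 0.0569 TPM, and did not pass the test (limma adjusted p = 0.7191).

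**Figure D1:**
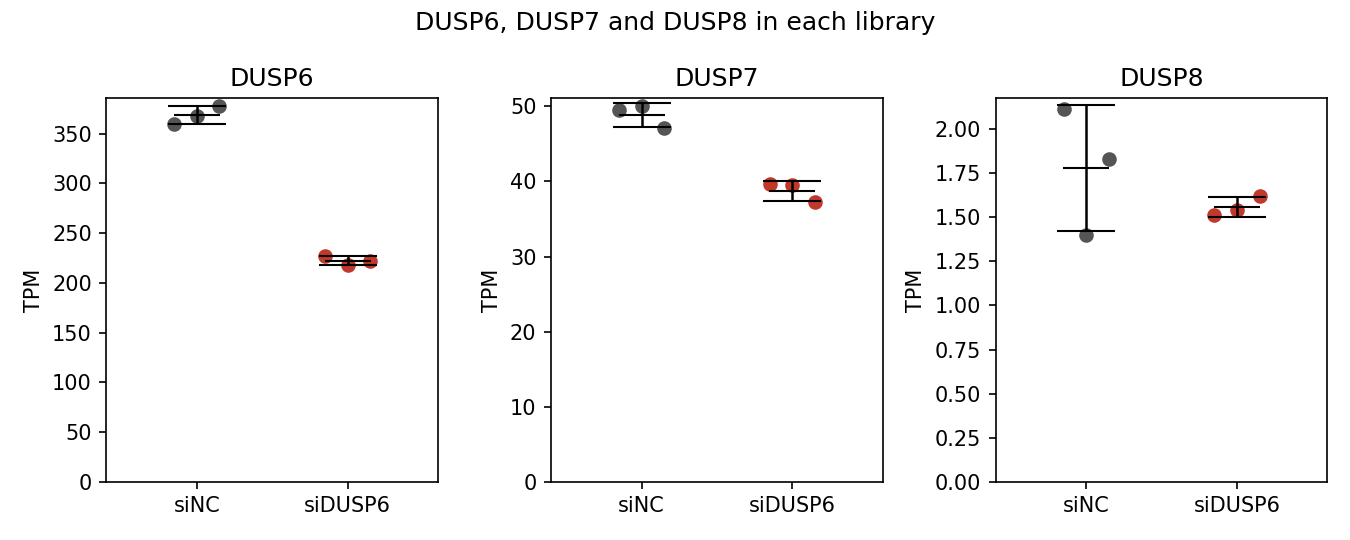
TPM of DUSP6, DUSP7 and DUSP8 (vertical axes, each from 0) in the siNC and siDUSP6 libraries; points are libraries, the middle line is the mean and the bars are 1 SD (n = 3). All 3 siDUSP6 libraries lie at 218 to 227 TPM of DUSP6, below the siNC libraries at 359 to 378 TPM.

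The largest rise among the named genes, of U2, is uncertain: it is 1 of 21 rows with that small nuclear RNA name, at 12.9, 11.2 and 56.3 TPM in the siDUSP6 libraries. TM4SF1, a cell surface protein, rose from 3.69 ± 0.285 to 8.10 ± 0.82 TPM (log2 fold change 0.9536, limma adjusted p = 0.004236). CXCL1, a neutrophil-attracting chemokine, rose from 69.0 ± 0.591 to 134 ± 4.38 TPM (log2 fold change 0.9494, SE 0.0313, limma adjusted p = 6.807e-05). PTGS2, the inducible cyclooxygenase, rose from 9.56 ± 0.436 to 18.2 ± 0.293 TPM. SOD2, the mitochondrial superoxide dismutase, rose from 387 ± 0.46 to 654 ± 9.24 TPM, and MMP1, the interstitial collagenase, from 679 ± 5.32 to 1141 ± 22.9 TPM. CXCL2, CXCL3, NCF1C, CCL8, MT1X and CXCL13 completed the 12 largest rises, of which NCF1C is uncertain as a near-identical copy of NCF1. Beside DUSP6, the 12 largest falls were those of PKDCC, SDHAF3, PRR5L, NUP214, SRPRB, PLCB2, AGAP4, MVD, DSCC1, ARMH1 and MCM2. Log2 fold changes of these ran from -0.68 for PKDCC to -0.43 for MCM2. Both rankings cover only called genes with a symbol, a mean of at least 5 TPM and non-overlapping groups. Of the 8 called genes higher and 2 lower by at least 2-fold, they hold only U2. SRPRB, a subunit of the signal recognition particle receptor, fell from 38.3 ± 1.63 to 26.7 ± 0.981 TPM. Among these 24 genes, U2, MT1X, CXCL13, PKDCC, SDHAF3, PRR5L, NUP214, PLCB2, AGAP4, MVD, DSCC1 and ARMH1 lost their call when at least 1 library was left out, with adjusted p up to 0.1426 over all alternatives.

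Of 14602 genes tested with limma, 346 were higher and 218 lower in siDUSP6 at an adjusted p under 0.05. Of these, 8 were higher and 2 lower by at least 2-fold, and 27 higher and 7 lower by at least 1.5-fold. The groups did not overlap for 25.1% of the genes, against 10% by chance. Higher genes made up 61.4% of the calls, and 72.0% after the TPM were rescaled by median-of-ratios factors. At an unadjusted p under 0.05 the balance was the other way, with 1173 higher and 1635 lower, and the median log2 fold change of all tested genes was -0.0254. The number of called genes was 222, 251 and 266 without siNC replicate 1, 2 and 3, and 241, 246 and 250 without siDUSP6 replicate 1, 2 and 3, against 564 with all libraries. It was 124 without the variance trend.

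**Figure D2:**
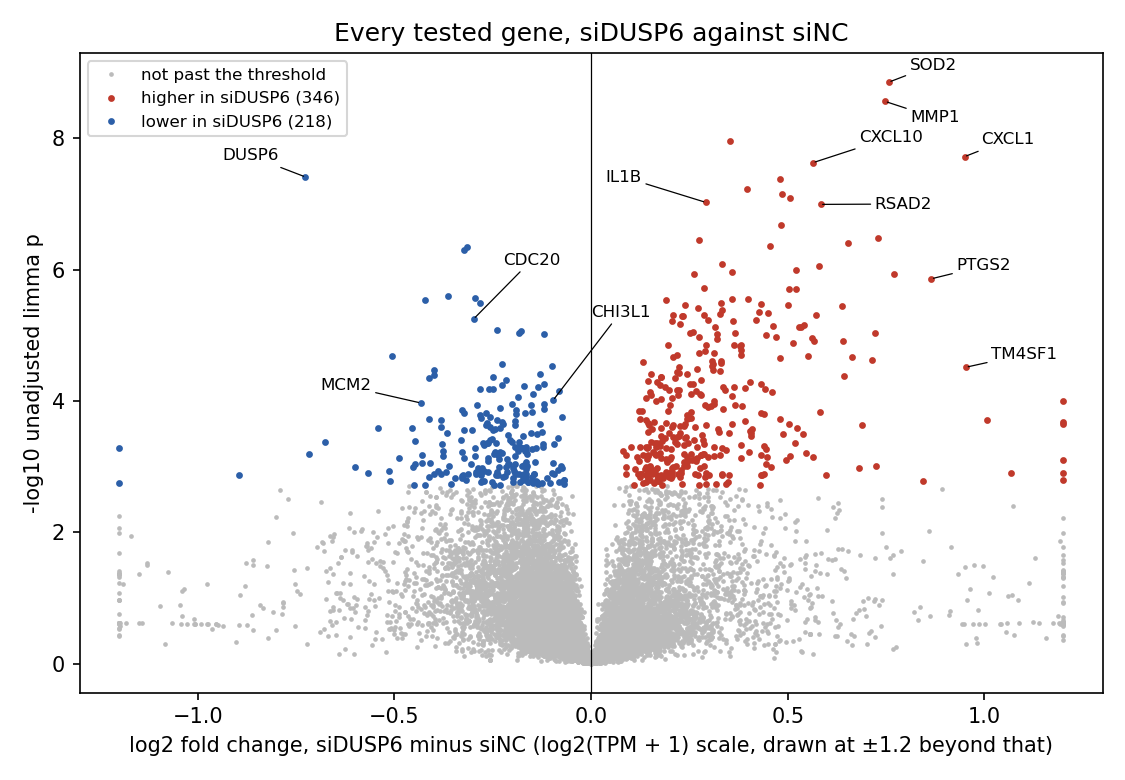
Each point is 1 of the 14602 tested genes, by its log2 fold change (horizontal axis, siDUSP6 minus siNC, log2(TPM + 1) scale) and -log10 of its unadjusted limma p (vertical axis). The 346 genes called higher are red and the 218 called lower are blue; DUSP6 is at -0.73 and CXCL1 at 0.95.

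Genes used as markers of M1, or classically activated, macrophages rose as a group. The list names 32 genes, of which 25 were measured. Of these 16 rose and 0 fell, or 19 and 0 adjusted over the list alone, with a median log2 fold change of 0.35. TNF rose from 35.4 ± 0.847 to 50.5 ± 1.06 TPM, IL1B from 4233 ± 47.2 to 5180 ± 42.4 TPM, and CXCL10, an interferon-induced chemokine, from 217 ± 2.74 to 322 ± 2.04 TPM. CCR7, a chemokine receptor of lymph node homing, rose from 11.7 ± 0.37 to 19.2 ± 1.33 TPM. CD80 stayed below the filter at 0.743 ± 0.197 and 0.75 ± 0.209 TPM, and CD86 measured 1.11 ± 0.19 and 1.03 ± 0.227 TPM (limma adjusted p = 0.8839). The list passed camera (adjusted p = 1.917e-24), also with an estimated correlation (adjusted p = 0.00559).

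Type I interferon response genes rose together, 23 of 33 measured members against 0 that fell, or 31 and 0 adjusted over the list alone, with a median log2 fold change of 0.30. RSAD2, an antiviral enzyme, rose from 140 ± 2.65 to 210.3 ± 3.26 TPM, OASL from 49.5 ± 2.58 to 72.5 ± 1.39 TPM and HERC5, an ISG15 ligase, from 30.4 ± 1.43 to 44.4 ± 0.168 TPM. Among NF-kB targets 13 of 25 rose and 0 fell, or 20 and 0 adjusted over the list alone, with a median of 0.27; CXCL2 rose from 44.2 ± 1.67 to 76.2 ± 3.71 TPM and CXCL3 from 102 ± 4.03 to 169 ± 4.37 TPM. Both lists passed camera (adjusted p = 8.197e-38 and 1.917e-24), also with an estimated correlation (adjusted p = 0.009137 and 0.00559). In a list of further chemokines 4 of 10 measured members rose and 0 fell, also adjusted over the list alone. The 4 were CCL8, CXCL6, CXCL12 and CCL7, and CXCL6 went from 44.8 ± 0.942 to 71.1 ± 1.71 TPM. The CXCL12 call was lost when any 1 library was left out and that of CCL7 in 5 of these fits. Their adjusted p reached 0.1498 and 0.102 over the alternatives that keep each gene. The chemokine list passed camera (adjusted p = 0.0005881) but not with an estimated correlation (adjusted p = 0.127). No tested gene stood in more than 1 of these 4 lists, which together held 93 tested genes, of which 56 rose.

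The measured markers of M2, or alternatively activated, macrophages showed no shared direction. The list names 36 genes, of which 19 were measured at a mean of at least 1 TPM. The others were too low to test, so a change in them is neither shown nor excluded. Of the 19, 2 rose and 2 fell, the same counts adjusted over the list alone, and 15 did not pass the test. MSR1, a scavenger receptor, rose from 287 ± 1.31 to 320 ± 3.66 TPM, and IL1RN, the interleukin-1 receptor antagonist, from 937 ± 4.91 to 992 ± 7.49 TPM. MERTK, a receptor for apoptotic cell uptake, fell from 47.4 ± 1.19 to 40.8 ± 1.08 TPM, and CHI3L1, a secreted chitinase-like protein, from 4454 ± 45.8 to 4167 ± 29.8 TPM. CD163 measured 27.8 ± 2.19 and 29.8 ± 0.676 TPM (limma adjusted p = 0.4286), while MRC1, ARG1 and IL10 stayed under 1 TPM in every library. The list's median log2 fold change was 0.04 (camera adjusted p = 0.6154), and it was -0.04 over genes with a mean of at least 5 TPM and -0.01 without siNC replicate 3. The MERTK and IL1RN calls were lost when any 1 library was left out, with adjusted p over all alternatives of up to 0.1225 and 0.2918. The MSR1 and CHI3L1 calls were kept in these fits but lost without the variance trend, and that of CHI3L1 also with no filter, with adjusted p over the alternatives that keep each gene of up to 0.1139 and 0.2366.

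ERK-responsive genes went both ways. Of 28 measured members other than DUSP6, 4 rose (IER3, DUSP4, DUSP5 and PLAUR) and 4 fell (SPRY2, SPRED1, SPRED2 and EGR2), or 5 and 6 adjusted over the list alone; PLAUR and SPRED2 are named to complete these counts, after their values were seen. IER3, an immediate early gene, rose from 138 ± 3.31 to 165 ± 6.13 TPM. SPRY2 and SPRED1, feedback inhibitors of the pathway, fell from 301 ± 6.12 to 259 ± 4.33 TPM and from 83.9 ± 1.69 to 70.7 ± 2.41 TPM. The list's median was 0.01 and its mean -0.01 (camera adjusted p = 0.75), and the median was -0.0031 without siDUSP6 replicate 3. Of the calls of IER3, SPRED1, EGR2, DUSP4 and DUSP5, each was lost when at least 1 library was left out, with adjusted p up to 0.1583 over all alternatives. That of SPRY2 was lost without the variance trend (up to 0.07721). Among 10 other MAP kinase phosphatases 3 rose (DUSP10, DUSP4 and DUSP5) and 1 fell (DUSP7), or 4 and 1 adjusted over the list alone (camera adjusted p = 0.2011). The DUSP10 call was lost when any 1 library was left out, with adjusted p up to 0.1152 over all alternatives. None of the 24 MAP kinase cascade genes passed limma's test over all genes or adjusted over the list alone (camera adjusted p = 0.7843); MAPK14, the p38 kinase, measured 44.3 ± 0.644 and 50.1 ± 2.35 TPM (unadjusted p = 0.005044).

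Cell cycle genes fell as a group by small amounts. Of 35 measured members 7 fell and 0 rose, or 27 and 0 adjusted over the list alone, with a median log2 fold change of -0.19. CDC20, an activator of the anaphase-promoting complex, fell from 188 ± 3.77 to 152 ± 0.577 TPM. MCM2 and MCM3, subunits of the replicative helicase, fell from 22.4 ± 1.06 to 16.4 ± 0.552 TPM and from 45.8 ± 0.276 to 37.9 ± 1.03 TPM, and TYMS, thymidylate synthase, from 58.3 ± 2.4 to 48.3 ± 1.31 TPM. The list passed camera (adjusted p = 1.994e-13), also with an estimated correlation (adjusted p = 0.009137). The TYMS call was lost when any 1 library was left out and the MCM3 call in 3 of these fits, with adjusted p up to 0.1014 and 0.08084 over all alternatives.

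Of 13 measured mitochondrially encoded genes 5 fell and 0 rose, or 8 and 1 adjusted over the list alone, with a median log2 fold change of -0.07, and MT-ND1, a complex I subunit, fell from 5107 ± 37.4 to 4702 ± 23.4 TPM. The median was -0.0187 after quantile normalization, which ended the calls of MT-ND2, MT-ND4 and MT-CO1 (adjusted p up to 0.6459, 0.3702 and 0.5812 over the alternatives that keep these genes). The MT-CO1 call was also lost when any 1 library was left out, and that of MT-ND1 without the variance trend (up to 0.163). All genes on the mitochondrial chromosome, listed or not, held 10.97% to 11.08% of all TPM in siNC and 10.51% to 10.74% in siDUSP6. The list passed camera (adjusted p = 9.415e-07), also with an estimated correlation (adjusted p = 0.04599). Nuclear-encoded oxidative phosphorylation genes (34 measured, 1 fell and 0 rose, or 2 and 0 adjusted over the list alone, median -0.04) and ribosomal protein genes (37 measured, 2 fell and 0 rose, or 4 and 0 adjusted over the list alone, median -0.0257) passed camera at adjusted p = 0.02545 and 0.01668. The ribosomal median is next to that of all tested genes (-0.0254). Neither list passed with an estimated correlation (adjusted p = 0.2371 and 0.127), after median-of-ratios scaling (0.203 and 0.5839), without the variance trend (0.1373 and 0.3357) or without siNC replicate 3 (0.08911 and 0.122). The oxidative phosphorylation list also fell short without siNC replicate 2 (0.05449) or siDUSP6 replicate 2 (0.05909) or 3 (0.1012). Over all alternatives adjusted p ranged from 0.001253 to 0.2371 and from 0.002904 to 0.5839.

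In the NRF2 and metal response list 5 of 17 rose and 2 fell, or 7 and 2 adjusted over the list alone; TXNRD1, thioredoxin reductase, rose from 144 ± 3.7 to 178 ± 3.98 TPM and HMOX1, heme oxygenase, from 171 ± 3.37 to 212 ± 7.09 TPM, while SLC30A1, a zinc exporter, fell from 27.4 ± 0.538 to 22.8 ± 0.348 TPM. In the inflammasome list 3 of 10 rose and 1 fell, or 4 and 1 adjusted over the list alone; AIM2, a DNA sensor, rose from 33.0 ± 1.02 to 45.2 ± 0.65 TPM and IL18 fell from 23.2 ± 0.647 to 17.6 ± 1.19 TPM. In the autophagy list 3 of 18 rose and 1 fell, or 6 and 1 adjusted over the list alone, and OPTN, an autophagy receptor, rose from 34.1 ± 0.855 to 44.7 ± 0.388 TPM. Heat shock genes (2 of 11 rose and 0 fell, or 4 and 0 adjusted over the list alone) included HSPA1B, which shares reads with its near-identical copy HSPA1A and is uncertain. MHC class I genes (2 of 15 rose and 1 fell, also adjusted over the list alone) included TAP1, a peptide transporter, which rose from 244 ± 3.4 to 285 ± 7.81 TPM. The medians of these 5 lists were 0.1301, 0.1561, 0.0766, 0.0473 and 0.0574. Their camera adjusted p values were 8.823e-05, 0.004514, 0.001836, 0.0005843 and 0.02545, and with an estimated correlation none passed (adjusted p = 0.2029, 0.127, 0.1156, 0.127 and 0.3305). The MHC class I list also fell short with fry (adjusted p = 0.06949), after quantile normalization (0.06234), without the variance trend (0.05116) and without siNC replicate 2 (0.06445) or 3 (0.08784). Its adjusted p ranged from 0.005132 to 0.3305 over all alternatives. The calls of SLC30A1, IL18 and HSPA1B were lost when at least 1 library was left out, with adjusted p up to 0.1018, 0.08508 and 0.09761 over all alternatives. So were those of NLRP3, CASP1, SQSTM1, MAP1LC3B, ATG3, HSP90AA1, HLA-E and HLA-C, with adjusted p up to 0.2864 over the alternatives that keep each gene. In the inflammasome, autophagy, heat shock and MHC class I lists only AIM2, OPTN and TAP1 kept their call in each of these fits. The calls of HMOX1 and TAP1 were lost without the variance trend (up to 0.05344 and 0.07804).

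**Figure D3:**
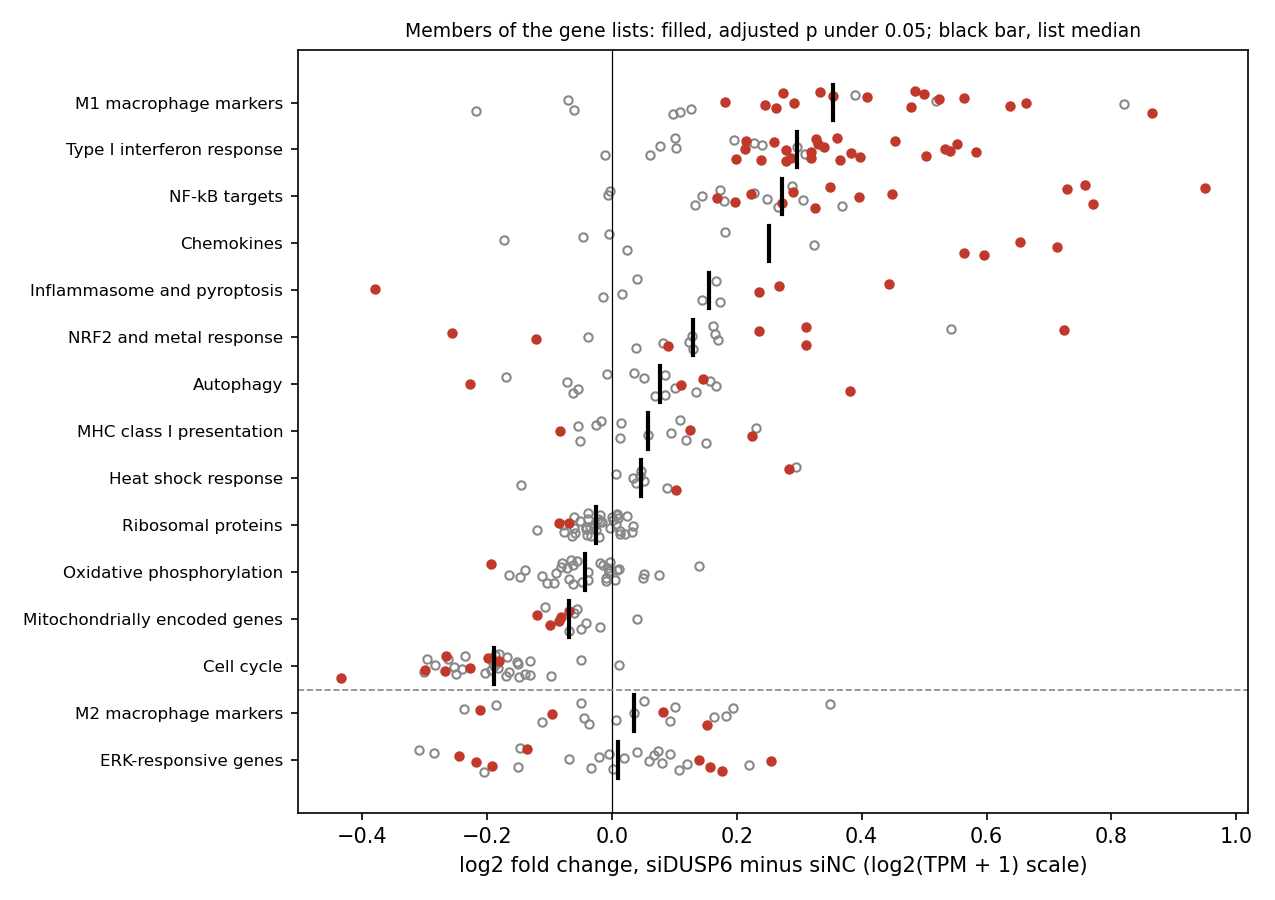
Log2 fold changes (horizontal axis, siDUSP6 minus siNC, log2(TPM + 1) scale) of the measured members of the 13 lists past the camera threshold and, below the dashed line, of the M2 and ERK lists. Filled points are genes with a limma adjusted p under 0.05, open points are the others, and black bars are list medians, from 0.35 for M1 markers to -0.19 for cell cycle genes.

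Of 27 measured secreted factors and proteases related to EMT 6 rose and 1 fell, or 7 and 4 adjusted over the list alone, with a median log2 fold change of 0.01. The list did not pass camera (adjusted p = 0.06031) but passed fry (adjusted p = 0.01528). It passed camera after median-of-ratios scaling (0.01613) and without siNC replicate 1 (0.03106) or siDUSP6 replicate 1 (0.03858), with adjusted p up to 0.5095 over all alternatives. Beside MMP1, the stromelysin MMP10 rose from 129 ± 6.62 to 190.3 ± 8.98 TPM, the collagenase MMP8 from 222 ± 0.67 to 299 ± 12.8 TPM and TIMP3, a metalloproteinase inhibitor, from 203 ± 5.02 to 237 ± 3.91 TPM, a call lost without the variance trend (adjusted p up to 0.08056 over all alternatives). The 1 that fell was MMP14, named after its values were seen, from 2181 to 1960 TPM (log2 fold change -0.154, limma adjusted p = 0.01762).

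Other lists did not pass camera, of which the stress response, receptor and cholesterol lists passed fry (adjusted p = 0.006824, 0.03322 and 0.04641; up to 0.2029, 0.4281 and 0.6858 over all alternatives). After median-of-ratios scaling the stress response and lysosomal lists passed camera (adjusted p = 0.02456 and 0.04796, the latter up to 0.7871 over all alternatives). The stress response list also passed with no filter (0.03858) or a mean of at least 5 TPM (0.047). In the unfolded protein and integrated stress response list 7 of 27 rose and 1 fell (adjusted p = 0.06393), with SLC7A11, a cystine transporter, going from 46.5 ± 0.681 to 62.5 ± 1.47 TPM and PSAT1 from 15.3 ± 0.11 to 11.6 ± 0.844 TPM. Among phagocytic and pattern-recognition receptors 2 of 18 rose, CD14 and TLR2, and 1 fell, ITGB2 (adjusted p = 0.1987), with TLR2 going from 139 ± 1.24 to 173 ± 4.16 TPM. The PSAT1 call was lost when any 1 library was left out and that of CD14 in 5 of these 6 fits, with adjusted p up to 0.1025 and 0.1146 over all alternatives. That of ITGB2 was lost without the variance trend (up to 0.147). Among 29 lysosomal genes 3 rose and 2 fell (adjusted p = 0.302), with the proteases CTSB and CTSL going from 1045 ± 6.03 to 1207 ± 20.1 TPM and from 1273 ± 19.3 to 1458 ± 21.5 TPM, calls lost without the variance trend (adjusted p up to 0.07527 and 0.08683 over all alternatives). Rises and falls numbered 2 and 1 of 21 p53 targets (adjusted p = 0.24), 1 and 2 of 23 cholesterol synthesis and uptake genes (adjusted p = 0.4966), 1 and 1 of 20 glycolysis genes (adjusted p = 0.75), 1 and 0 of 14 hypoxia genes (adjusted p = 0.5313), 1 and 0 of 9 complement genes (adjusted p = 0.7659) and 0 and 1 of 5 MHC class II genes (adjusted p = 0.6154). Every p53, glycolysis and MHC class II call was lost when any 1 library was left out. The hypoxia call (ADM) was lost in 5 of these fits and the complement call (C5AR1) in 3. Of the cholesterol genes only INSIG1 kept its call in each of these fits. Adjusted over the list alone, rises and falls numbered 7 and 2 for the stress response list, 3 and 2 for receptors, 5 and 3 for lysosomal genes, 2 and 1 for p53 targets, 2 and 4 for cholesterol genes, 1 and 1 for glycolysis, 1 and 1 for hypoxia, 1 and 0 for complement and 0 and 2 for MHC class II. No member passed over all genes among 12 LXR targets (adjusted p = 0.8224), of which 2 rose adjusted over the list alone, 10 fatty acid synthesis genes (adjusted p = 0.906), 9 replication-dependent histones (adjusted p = 0.6088) and 11 genes of the siRNA machinery (adjusted p = 0.75).

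Lists of markers of other cell types did not pass camera, with 3 to 8 members measured in each. This does not show that they did not differ. Of 8 measured stromal and mesenchymal markers 1 rose, NT5E, from 276 ± 2.61 to 323 ± 2.41 TPM, and the rest did not pass (median -0.1077, camera adjusted p = 0.8224), with the same count adjusted over the list alone. None of 3 epithelial markers (median -0.0495, camera adjusted p = 0.75), 4 neutrophil and dendritic cell markers (-0.1549, 0.7307), 4 precursor genes of undifferentiated THP-1 cells (-0.0638, 0.2495) or 7 lymphocyte and endothelial markers (-0.0921, 0.7307) passed over all genes, and 1 of the last, TRAC, fell adjusted over the list alone, from 64.8 ± 1.22 to 56.2 ± 2.79 TPM (limma adjusted p = 0.05749 over all genes). The NT5E call was lost without the variance trend (adjusted p up to 0.06366 over all alternatives). With no filter on low TPM the precursor list passed camera (adjusted p = 0.03867, up to 0.5671 over all alternatives).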

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

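DUSP6 kept its direction and call in all alternatives (-0.7447 to -0.7058, adjusted p 1.536e-05 to 0.01198), as did the medians of the M1 (0.2829 to 0.3814), interferon (0.2635 to 0.3166), NF-kB (0.2318 to 0.2935) and cell cycle (-0.213 to -0.1554) lists, and that of the mitochondrially encoded list (-0.0775 to -0.0187) in all but TPM without mitochondrial and top 50 genes, which leaves it no member. That alternative also gives no value for the named mitochondrial genes, IL1B and CHI3L1. A mean of at least 5 TPM gives none for CD1C, CD1E, CD86, CXCL12, DUSP8, H2AC8, KRT7, MYB, NKG7 and the epithelial, MHC class II, precursor, and neutrophil and dendritic cell lists, and protein-coding genes only gives none for NCF1C, SOD2, TRAC and U2. Against 346 higher and 218 lower genes, no variance trend gave 106 and 18, no filter on low TPM gave 114 lower genes, and leaving out 1 library gave 165 to 192 higher and 57 to 79 lower genes. Leaving out a library removes samples from the fit; for the other settings the cause was not tested. Between 317 and 353 of the 564 calls were lost without 1 library, and 0 changed sign. With an estimated correlation 5 instead of 13 lists passed camera. DUSP7 was no longer called with no variance trend (-0.3271, adjusted p = 0.05978), and it ranged from -0.3532 to -0.2986 when 1 library was left out. Of 99 called genes named by the rule, 28 kept the call in every alternative that gave a value, 45 kept it whichever library was left out, and 0 changed sign.

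Same-numbered libraries did not deviate together (correlations of deviations from the group means 0.0134, -0.024 and 0.0601), so the replicate numbers were not taken to pair the samples, and not every library correlated best with the one of its own number. With the replicate block 101 genes were higher and 20 lower, and 120 of these 121 were among the 564.

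The sign of 15 list medians changed in at least 1 alternative, in 37 pairs of list and alternative; 0 of these lists passed camera, and their medians were at most 0.0921 in size. Median-of-ratios scaling moved the median of all tested genes from -0.0254 to -0.0073. Sign changes of medians near 0 in that setting therefore go with a shift of all genes. For the other settings the cause of the sign changes was not tested. The M2 median (0.0354) was -0.0369 with a mean TPM of at least 5 and -0.0084 to 0.0388 without 1 library, and the ERK median (0.0102) was -0.0031 to 0.0262 without 1 library. With median-of-ratios scaling the medians were 0.0046 for the MAP kinase cascade, 0.0135 for fatty acid synthesis, 0.0020 for hypoxia, 0.0136 for MHC class II and 0.0035 for histones. With quantile normalization they were 0.0004 for the MAP kinase cascade, 0.0077 for hypoxia and 0.0265 for MHC class II. Without mitochondrial and top 50 genes hypoxia was at 0.0169. With no filter on low TPM hypoxia was at 0.0301, phagocytic receptors at -0.0289 and histones at 0.0030, and with protein-coding genes only the lymphocyte and endothelial list was at 0.0152.
Without 1 library, medians ranged from -0.0052 to 0.0569 for other MAP kinase phosphatases, -0.0176 to 0.0010 for the MAP kinase cascade, -0.0010 to 0.0274 for EMT factors, -0.0419 to 0.0042 for LXR targets, -0.0319 to 0.0206 for fatty acid synthesis, -0.0185 to 0.0211 for hypoxia, -0.0115 to 0.0112 for lysosome, -0.1210 to 0.0945 for MHC class II, -0.1742 to 0.0587 for epithelial markers, -0.0276 to 0.0659 for histones and -0.1193 to 0.0050 for siRNA machinery. Of single genes, CD1C ranged from -0.2466 to 0.0131 and CD86 from -0.1498 to 0.0031; neither was called. TPM keep no depth, so what depth limits could not be measured.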

Other observations

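The tests on the actin cytoskeleton, the treatment labels, the seed site classes and the sites of every seed were chosen only after the results they concern were seen. Of genes named after their values were seen, the integrin ITGB1 fell from 480.2 to 386 TPM (log2 fold change -0.32), vinculin (VCL) from 42.3 to 31.5 TPM (-0.41), drebrin (DBN1) from 32.1 to 24.1 TPM (-0.40) and fascin (FSCN1) from 107 to 89.2 TPM (-0.26). ACTB and ACTG1 fell by 0.12 and 0.15 on the log2 scale. TPM4, a tropomyosin, rose from 412 to 575 TPM (0.48), as did MARCKS. A shared fall of actin cytoskeleton and adhesion genes is not shown. A list of 62 of them was written after the called genes were seen. Its 14 falls against 2 rises and its camera p (0.004352 with the preset correlation, 0.2025 with an estimated one) thus restate what was seen. The list's median was -0.0359, against -0.0254 for all tested genes. Of its 62 members 39 were below 0, against 57.86% of all tested genes. The 46 members that were not called had a median of -0.0063. Leaving out the called members, mostly falls, moves the median up whatever the cause, so this value decides nothing.

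The rise of NF-kB and interferon genes was set against technical explanations. After quantile normalization both medians lay at least 0.2987 above that of all genes (2 other rescalings, by a factor per library, move genes nearly alike and test little here), and after a transcript length trend was removed the lower was 0.2685, which argues against scaling and length as the whole cause. Silencing of most of these genes in siNC through a seed of the control siRNA cannot be told apart from other causes: the 7-mer with the highest z, AACGGCC, in 0 of the 35 called members with a 3' UTR, is in 1.46% of all genes and did not pass the correction (Bonferroni 0.4563), so its absence was nearly fixed and the bound set on it before was wrong, and over 7-mer sites of every seed the excess of carriers among the 35 over the share expected from 3' UTR length and GC content had upper 95% bounds of up to 58.29%. Innate sensing that differs between the siRNAs cannot be told apart from an effect of DUSP6, since the titles name 1 siRNA per group. IFNB1 was near the floor, at a mean of 0.45 TPM in siDUSP6, and does not decide it. An effect of lower DUSP6 stays open beside innate sensing, a seed of the control siRNA and other effects of the siRNAs. The design does not exclude further causes.

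The falls were weighed in the same way. The cell cycle median lay -0.161 from that of all genes after quantile normalization and was -0.1897 after the length trend was removed, which argues against both as the whole cause. A seed match of the antisense strand of a DUSP6 siRNA as the source of most falls is argued against by the sites of the 3676 seeds that mRNA allows, whose excess of carriers among the 195 called lower genes with a 3' UTR had upper 95% bounds of at most 28.78%. The 7-mer of that mRNA with the lowest z, AGTTTGA, was carried by 15.9% of the 195 and by 19.4% of all genes, but its own shift did not pass the correction (z = -3.81, Bonferroni 0.5115), so it is not shown to be a seed site. Lower DUSP6, other effects of the siRNA and further causes stay open.

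The 7-mers with the lowest z of all 16096 scanned, CACAGTT (shift -0.0225) and ACAGTTA (-0.0231; z = -5.35 and -5.30 across genes, Bonferroni 0.001419 and 0.001896, where shuffled genes gave an absolute z of up to 5.144), overlap as sites of 1 seed, AACTGTG. The 265 genes with the full site CACAGTTA lay -0.0466 ± 0.0093 (SE) from genes with no site. Those with a single 7-mer lay at -0.0199 and -0.0202 and those with the 6-mer at -0.0065 (permutation p = 0.10461). Each site class had this direction in all 3 siDUSP6 libraries, but these were set against the same siNC mean, so they are not separate tests. The permutation p of the full site was 1e-05, the smallest that 100000 permutations can give. The seed was picked from these same genes and was 1 of 5 seed explanations tested, so this p overstates the evidence. In 50 overlapping random halvings of the genes a site of this seed led the first part in 29, with a negative shift in the other part in 29 of these. Another 7-mer led in 21, negative in 11. The halvings reuse the genes that picked the seed, so a negative shift of its sites in the other part was nearly fixed. They are not separate evidence for the seed. A candidate explanation is a small RNA with this seed that is more active in the siDUSP6 libraries, such as the sense strand of the siRNA, whose sequence was not used here: AACTGTG occurs once in the DUSP6 mRNA, in the coding sequence of exon 3 (chromosome 12, 89349538 to 89349544, GRCh38), but 22.6% of the scanned 7-mers occur in that mRNA. The full site was carried by 22 called lower genes, 8.3% of its carriers against 1.89% of genes with no site, so it could account for few of the falls, and DUSP7 has no site.

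Another siRNA in siDUSP6 replicates 2 and 3, as their treatment fields read, is argued against by DUSP6, which was at most 222 TPM in both, next to 227 TPM in replicate 1 and below every siNC library.

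Whether chance can be excluded cannot be shown, since 3 against 3 libraries make 10 splits. The real split called 564 genes against at most 4 in any other, 346 higher against at most 2 in 1 direction, 218 lower against at most 2, and 13 lists against at most 8; in each case 1 of the 10 splits, the real one, gave a result as large. Camera with the preset correlation called lists in splits with almost no called gene, but these splits are not free of a group difference. Each mixes the groups unevenly, so part of any siDUSP6 difference stays between the sides and the rest widens the spread within them. The other splits thus do not show how many genes or lists would be called with no difference.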
